A study of Mus musculus with 24 samples.

How the data were processed

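RNA was sequenced from liver and inguinal white adipose tissue of mice that carried a knockout of Mrs2 (KO) or did not (WT) and were fed chow or a Western diet (WD). Per the labels, libraries were made from RNA captured on poly-T beads and read from both ends, so they sample polyadenylated RNA, and the mitochondrial transcripts among them only as far as these carry a tail. The submitters' processing notes name HISAT2 2.0.5, DESeq2 1.20.0 and the mouse genome build mm10 without giving their roles. The read counter and the strandedness of the libraries are not given in the sources used here.

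The values analysed were the authors' FPKM, the fragment count scaled by gene length and library size, of 54532 genes in 24 libraries, per the file headers. Gene length in bases was deposited beside them in the same table, per the file headers. The authors' 4 tables of KO against WT hold read counts, per the file headers, for the genes with an unadjusted p under 0.05. Those deposited tables also hold the authors' log2 fold change of KO over WT. The authors' p-value and adjusted p-value stand beside it, per the file headers, which do not name the test. A further 32 columns of values per library or group in the authors' tables, which hold their normalized counts, were not used.

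Multiplying each FPKM by the gene length and by 1 constant per library gave whole reads within 0.01 reads for all 540911 values above 0 (100%). All 64434 deposited counts that could be compared equalled the reads recovered in this way. The constant was not the library's total: the effective library size was 0.769 to 1.07 times the recovered reads in liver and 1.24 to 1.60 times in adipose tissue. The deposited FPKM therefore already carry a scaling factor per library. In liver the group mean of this ratio was 1.02 ± 0.0465 (SD, n = 3) in WT WD and 0.781 to 0.816 in the other 3 groups. A spreadsheet had turned 27 gene symbols into dates, and genes were therefore joined by identifier. Positions are those of the deposited table, on mm10. Of 54409 identifiers present in the GENCODE vM21 annotation, 98.3% had equal coordinates there.

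The labels describe the 3 libraries of each group as biological replicates, and no pair within a group differed as little as read counting alone would give. That does not tell separate pieces of tissue of 1 animal from separate animals. Pearson's r across genes was 0.927 to 0.978 within groups, and the squared difference between replicates was 19.0 to 82.0 times that of read counting. Equal replicate numbers were not treated as pairs, since nothing in the labels pairs them. Residuals of equal numbers correlated above 0.1 in every pair only for KO against WT on chow in adipose tissue (r = 0.184, 0.127 and 0.407 across genes), where number 2 correlated better with another number (0.258). For that comparison a fit with a replicate block is given beside the result. Residuals of liver and adipose libraries with equal group and number correlated at 0.0227 to 0.494 across genes, all above 0. Unequal numbers were not compared between the tissues, so a pair of libraries from 1 animal is neither shown nor excluded. No fit took the tissues as paired.

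The tissues were fitted apart, each with its 4 groups in 1 model. Genes with a mean FPKM of at least 0.5 over the 12 libraries of a tissue were tested, which left 14019 genes in liver and 14685 in adipose tissue. The test was limma 3.58.1 on log2(FPKM + 1), with a variance trend and a robust prior, in R 4.3.3. P-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene with an adjusted p under 0.05 was called. Log2 fold changes are given with their standard error from that fit, and the pseudocount of 1 shrinks the fold change of genes near 0. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were run as alternatives. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

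Altogether 37 gene lists (pathways, complexes and cell type markers) were fixed before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. Lists with at least 5 tested members, 35 in liver and 32 in adipose tissue, were tested with camera at a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. Camera asks whether a list's genes moved further than the other genes. No call of camera in any of the 10 comparisons held with a correlation estimated from the data, and that adjusted p is given beside each call. In every called list the mean, the median and the test had 1 sign.

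Genes are named by rule. In each comparison of KO with WT these are Mrs2 and the 10 largest rises and 10 largest falls among called genes. Such genes had no overlap between the groups' libraries, a mean FPKM of at least 3 in the higher group and a symbol that is not a clone or model name. For each called list, and for 8 lists in any case, up to 4 members with the smallest p were added. For diet comparisons and interactions the numbers were 6, 6 and 3, and the rule on overlap was not applied to the interactions. A gene outside the rule is said to be chosen after its values were seen. Libraries left out for their marker genes, by a list level above the tissue median by more than 2 on the log2 scale, or 0.8 for lymphocyte genes, were chosen after the values were seen, and so were these alternatives. The limit of 0.8 was set last, at a level that left out the same 3 libraries as an earlier rule.

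The tests were also run on simulated reads with the means, depths and dispersions of the real libraries and 200 genes changed by a log2 of 1 or 2. Nuclear genes of oxidative phosphorylation were raised as a list as well. Each gene was drawn apart from the others, from 1 mean over the libraries of the tissue. Correlation between genes and libraries high in markers of another tissue were thus absent, and the shares below hold for such reads only. For KO against WT on WD, 36.7% of changes of a log2 of 1 and 80.8% of those of 2 were recovered in liver, and 44.4% and 76.0% in adipose tissue. For KO against WT on chow the shares were 35.1% and 72.0% in liver and 31.0% and 73.7% in adipose tissue. The interaction of genotype and diet gave 6.06% and 61.9% in liver and 7.07% and 57.7% in adipose tissue. No changed gene was called with the wrong sign.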

Results

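The series asks how uptake of magnesium into mitochondria shapes metabolism under an obesogenic diet. Mrs2 is the magnesium channel of the inner mitochondrial membrane. KO and WT mice received chow or WD for 52 weeks from 13 weeks of age, and RNA was taken from 50 mg of liver and 100 mg of inguinal white adipose tissue (iWAT), a depot under the skin from which the lymph nodes had been removed. Each combination of genotype, diet and tissue held 3 mice, which made 8 groups and 24 libraries. The recovered reads per library numbered 14.7 to 19.5 M in liver and 15.4 to 20.4 M in iWAT. The 20 genes with the most reads took 18.8% to 26.5% of the reads in liver and 14.3% to 22.1% in iWAT. Mitochondrially encoded genes took 3.08% to 4.83% of the reads in liver. In iWAT their share was 4.21% ± 0.587 (SD, n = 3) in WT chow, 6.12% ± 0.389 in KO chow, 3.07% ± 0.503 in WT WD and 9.07% ± 3.35 in KO WD. In the first principal component of liver, which held 35.6% of the variance, the 3 WT WD libraries lay at -60.6, -34.8 and -48.2 and the other 9 at -1.26 to 29.7.

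Mrs2 (ENSMUSG00000021339, mm10 chromosome 13, 24987483 to 25020379, minus strand) was lower in KO than in WT libraries on both diets in iWAT and on chow in liver, but not on WD in liver. In iWAT on chow it stood at 4.48, 4.67 and 3.87 FPKM in the WT libraries and at 2.05, 1.74 and 2.25 in the KO libraries. On WD it stood at 5.01, 2.74 and 4.72 in WT and at 1.95, 1.68 and 1.60 in KO. In liver on chow the WT libraries held 6.26, 5.87 and 6.50 FPKM and the KO libraries 3.90, 4.47 and 4.16. On WD the livers labelled WT held 5.10, 4.10 and 5.11 FPKM and those labelled KO 4.10, 5.21 and 4.21, so that WT replicate 2 lay below all 3 labelled KO (4.096 against 4.102 or more) and KO replicate 2 above all 3 labelled WT. The log2 fold change of KO over WT was -0.82 ± 0.16 (SE, n = 3 per group) on chow and -0.88 ± 0.16 on WD in iWAT, and -0.48 ± 0.10 on chow and -0.07 ± 0.10 on WD in liver. By limma, WD in iWAT passed the threshold (adjusted p = 0.0234), and the other 3 did not (adjusted p = 0.432 on chow in iWAT, 0.863 on chow and 0.692 on WD in liver). The call on WD in iWAT ended without KO replicate 1 or 2 (-0.93 and -0.86, adjusted p = 0.0890 and 0.0969) and without WT replicate 1 or 3 (-0.75 and -0.79, adjusted p = 0.0550 and 0.105). Over the magnesium transport list alone, adjusted p on chow was 0.0069 in iWAT and 0.013 in liver. In the authors' deposited values, by a test that the headers do not name, Mrs2 on chow in iWAT stood at -1.09 with an adjusted p of 8.15e-06. A gene-level sum over 7621 exonic bases does not show whether an exon is missing. Of these bases, 2466 (32.4%, 24990036 to 24992501) in the 3′ untranslated region are shared with the opposite strand's Gpld1, which stood at 75.1 ± 5.28 (SD, n = 3), 65.6 ± 1.80, 39.3 ± 2.54 and 61.4 ± 8.64 FPKM in liver of WT chow, KO chow, WT WD and KO WD. In recovered reads, Mrs2 on WD stood at 625, 504 and 630 in the livers labelled WT. Those labelled KO held 394, 541 and 377, at depths of 14.7 to 16.6 M in these 6 livers. Before the deposited scaling, WT replicate 2 thus lay above KO replicates 1 and 3, and KO replicate 2 below WT replicates 1 and 3. The order in FPKM therefore depends on the scaling, though the labels overlap in both. Because Mrs2 in liver on WD did not separate by label, directions there are given as those of the livers labelled KO or WT.

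**Figure D1:**
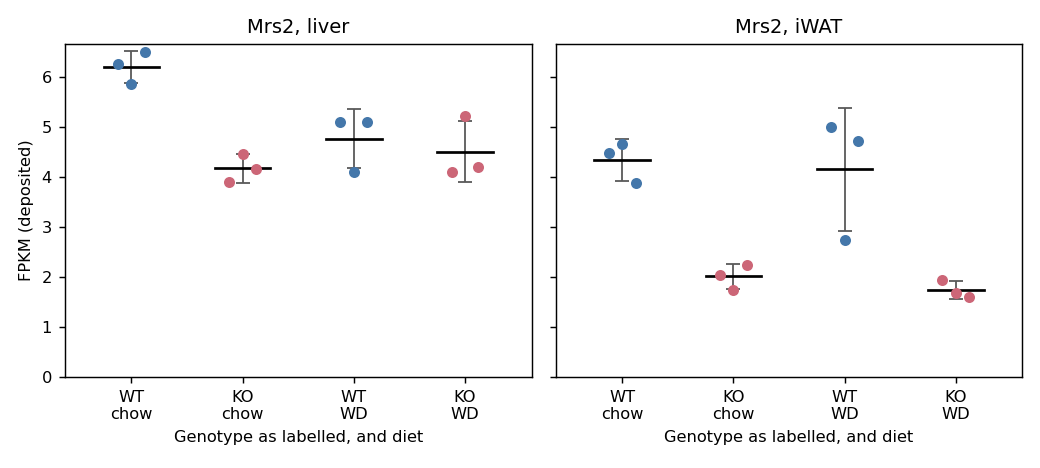
Mrs2 in FPKM in each of the 24 libraries, with the mean and SD of each group of 3 mice, in liver and iWAT. The KO libraries lie below the WT libraries in iWAT on both diets and in liver on chow, and on WD in liver the labels overlap (4.10 to 5.21 FPKM in KO, 4.10 to 5.11 in WT).

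Markers of other tissues stood out in single libraries. Acinar genes of the pancreas, at 0.21 or less as a mean log2 level in the other livers, reached 7.12 in KO chow replicate 1 and 6.84 in WT WD replicate 2, where trypsinogen Prss2 stood at 264 and 198 FPKM. Skeletal muscle genes stood out in liver in WT chow replicate 3 and KO WD replicate 2, where the actin Acta1 stood at 72.7 and 27.7 FPKM, and less so in KO chow replicate 2 (7.60 FPKM). In iWAT they did so in WT WD replicate 1 and KO WD replicate 1 (828 and 383 FPKM). Lymphocyte genes were highest in iWAT of WT chow replicate 3, KO chow replicate 3 and KO WD replicate 2, at mean log2 levels of 4.10, 3.95 and 3.30 against 2.82 or less in the other 9. Red cell genes were highest in iWAT of WT WD replicate 1, where the globin Hbb-bs stood at 4105 FPKM. Every library read as male, with the female-specific Xist at 0.0354 FPKM or less and the Y-linked Ddx3y at 12.6 FPKM or more.

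**Figure D2:**
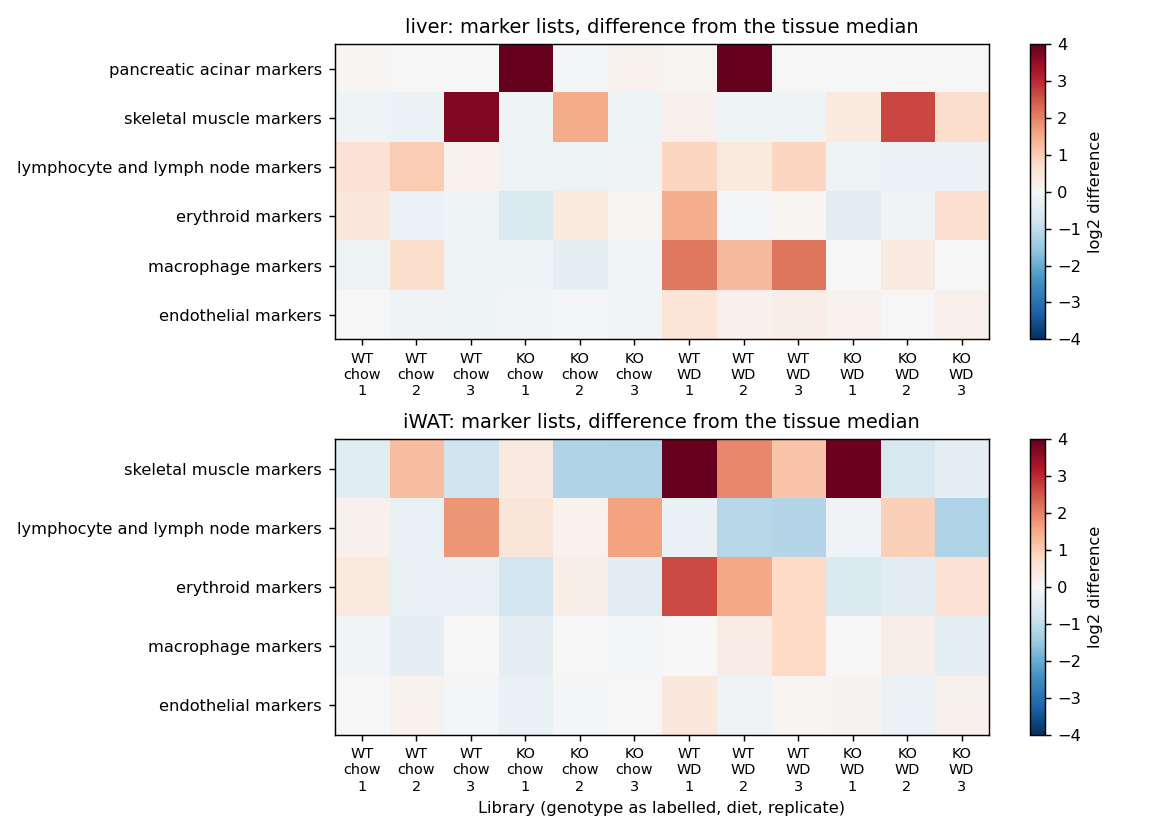
Heat map of the mean log2(FPKM + 1) level of marker lists in each library as a difference from the tissue's median, with colours limited at -4 and 4. Acinar genes stand out in 2 livers, muscle genes in 2 livers and 2 iWAT libraries, and lymphocyte genes in 3 iWAT libraries, while macrophage genes are high in the 3 livers labelled WT WD.

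The comparison of KO with WT liver on chow asks what loss of Mrs2 does without dietary stress. Genes of the extracellular matrix stood lower in KO livers, with 30 of 31 members below 0 and a mean log2 fold change of -0.421 (camera adjusted p = 2.2e-10, and adjusted p = 0.75 with an estimated correlation). Fibrillar collagen Col3a1 stood at -0.995 ± 0.33 (SE, n = 3 per group) and Col1a1 at -0.82 ± 0.37. Lymphocyte genes were lower in 10 of 10 members, by a mean of -0.752 (camera adjusted p = 2.6e-09, and adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone, those that passed included the B cell genes Ighd (-0.90 ± 0.21) and Cd79a (-1.16 ± 0.31) and the T cell gene Cd2 (-0.41 ± 0.15). Nuclear genes of oxidative phosphorylation (OXPHOS) stood higher in 69 of 71 members, by a small mean of 0.137 (camera adjusted p = 2.2e-10, and adjusted p = 0.75 with an estimated correlation), and Ndufa8 of complex I stood at 0.25 ± 0.09.

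No single gene passed in chow-fed liver. With limma 0 of 14019 genes were called, the smallest adjusted p was 0.863 and 675 genes had an unadjusted p under 0.05, while edgeR called 0 and DESeq2 16. Groups did not overlap in 8.92% of genes, where chance gives 10%. Limma's count was 2 without WT replicate 3, which was high in muscle genes, and 3 with no filter on low values. Camera called 13 of 35 lists (5 higher, 8 lower), and the 3 lists above kept their calls without any single library of the 6. Of the other 10, inflammation genes had a mean of -0.536 (camera adjusted p = 2.6e-05, and adjusted p = 0.75 with an estimated correlation), with the chemokine Ccl2 at -0.82 ± 0.25, but at -0.223 the call ended without WT replicate 2 (adjusted p = 0.176). That library's absence ended 7 list calls in all (adjusted p = 0.118 to 0.923), that of KO replicate 2 ended 5 (0.0714 to 0.661) and that of WT replicate 1 ended 3 (0.143 to 0.995). Acinar genes, at a mean of 2.37, followed the 1 library in which they stood out and lay at 0.0331 without it (adjusted p = 0.999).

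On WD the comparison of KO with WT asks whether loss of Mrs2 alters the state of the liver after the prolonged diet. Markers of macrophages and scar tissue fell steeply in the livers labelled KO. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, stood at 30.1 ± 12.4 FPKM (SD, n = 3) in those labelled WT and at 0.571 ± 0.433 in those labelled KO, a log2 fold change of -4.26 ± 0.33 (SE; limma adjusted p = 0.000167). The lipid receptor Trem2 fell by 2.52 ± 0.29, the macrophage elastase Mmp12 by 3.36 ± 0.40 and the lysozyme Lyz2 by 3.06 ± 0.47. Of 24 macrophage genes 19 fell and none rose, with a mean of -1.74 (camera adjusted p = 2.6e-14, and adjusted p = 0.213 with an estimated correlation). Of 31 matrix genes 27 fell and 1 rose, with a mean of -1.501 (camera adjusted p = 1.1e-20, and adjusted p = 0.187 with an estimated correlation). Among them the proteoglycan Lum fell by 2.89 ± 0.29, the protease Mmp2 by 1.88 ± 0.20 and the collagen crosslinker Loxl1 by 1.40 ± 0.14.

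Other cell markers moved the same way. Inflammation genes fell in 14 of 21 members (mean -1.47, camera adjusted p = 2.9e-10, and adjusted p = 0.213 with an estimated correlation), among them Ccl2 by 2.28 ± 0.25 and the interleukin antagonist Il1rn by 1.68 ± 0.21. Of 11 genes of liver tumours and fetal liver 7 fell (mean -1.96, camera adjusted p = 3.4e-07, and adjusted p = 0.187 with an estimated correlation), with the transcription factor Sox4 down by 1.24 ± 0.13. Bile duct genes fell in 7 of 8 members (mean -0.938, camera adjusted p = 3.2e-05, and adjusted p = 0.187 with an estimated correlation), including Epcam by 1.32 ± 0.11. Lymphocyte genes fell in 6 of 10 (mean -0.942, camera adjusted p = 0.00013, and adjusted p = 0.213 with an estimated correlation), including Cd79b by 1.15 ± 0.24. Cell cycle genes fell in 9 of 15 (mean -0.695, camera adjusted p = 5.9e-06, and adjusted p = 0.213 with an estimated correlation), including the DNA replication helicase subunit Mcm3 by 0.60 ± 0.13. Stellate cell and fibroblast genes fell in 4 of 13 and rose in 2 (mean -0.487, camera adjusted p = 0.0021, and adjusted p = 0.213 with an estimated correlation), with the growth factor receptor Pdgfrb down by 1.35 ± 0.11 and the hedgehog binding protein Hhip up by 0.69 ± 0.11. Endothelial genes fell in 3 of 15 and their list was not called (camera adjusted p = 0.083).

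Enzymes and transporters of hepatocytes rose in the livers labelled KO. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), a steroid dehydrogenase typical of male liver, stood at 184 ± 113 FPKM (SD, n = 3) against 0.826 ± 0.647, a rise of 6.57 ± 0.43 (SE; limma adjusted p = 3.51e-05). The organic anion transporter Slco1a1 rose by 3.66 ± 0.21. Male-biased and Y-linked genes, tested as 1 list, rose in 8 of 13 members (mean 2.07, camera adjusted p = 3.2e-05, and adjusted p = 0.187 with an estimated correlation). Several major urinary protein genes were among the largest rises, such as Mup13 (7.33 ± 1.05) and Mup7 (6.95 ± 1.497), but the members of this family are so alike that reads cannot be assigned to 1 of them with certainty. Bile acid genes rose in 12 of 23 and fell in 1 (mean 0.826, camera adjusted p = 9.8e-06, and adjusted p = 0.187 with an estimated correlation), with the bile salt importer Slc10a1 up by 1.66 ± 0.20 and the hydroxylases Cyp7b1 and Cyp27a1 by 2.13 ± 0.29 and 1.05 ± 0.14. Xenobiotic genes rose in 9 of 20 (mean 0.879, camera adjusted p = 0.00053, and adjusted p = 0.387 with an estimated correlation), including Cyp2c29 by 2.15 ± 0.31. Hepatocyte markers rose in 10 of 20 (mean 0.522, camera adjusted p = 0.00044, and adjusted p = 0.277 with an estimated correlation), but the mean was 0.439 after median-of-ratios scaling and -0.136 after quantile normalization, which turned the direction.

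Mitochondrial genes rose as well. Nuclear OXPHOS genes rose in 31 of 71 members (mean 0.312, camera adjusted p = 2.5e-11, and adjusted p = 0.299 with an estimated correlation), with the ATP synthase gene Atp5o up by 0.40 ± 0.08 and Ndufs3 of complex I by 0.46 ± 0.09. Fatty acid oxidation genes rose in 9 of 33 and fell in 1 (mean 0.465, camera adjusted p = 0.0001, and adjusted p = 0.478 with an estimated correlation), with the carnitine transferase Cpt2 up by 0.79 ± 0.14. TCA cycle genes rose in 7 of 24 and fell in 1 (mean 0.295, camera adjusted p = 0.0005, and adjusted p = 0.478 with an estimated correlation). Mitochondrially encoded OXPHOS genes rose in 6 of 13 (mean 0.619, camera adjusted p = 0.001, and adjusted p = 0.454 with an estimated correlation), but mt-Nd5 and mt-Nd6 turned after quantile normalization, to -0.250 and -0.0603. All 4 of these list calls, and that of the hepatocyte markers, ended after that normalization. HIF1A targets fell in 6 of 24 and rose in 1 (mean -0.236, camera adjusted p = 0.04, and adjusted p = 0.299 with an estimated correlation), with hexokinase Hk2 down by 1.56 ± 0.16. That list's call ended without WT replicate 1 (-0.175, adjusted p = 0.106) or KO replicate 3 (-0.233, adjusted p = 0.0546). Of 24 lipogenesis genes 3 rose and 1, Scd2, fell by 1.496 ± 0.28 (list mean 0.185, of the opposite sign after quantile normalization), and of 25 cholesterol synthesis genes 3 rose, such as Tm7sf2 by 1.08 ± 0.16 (camera adjusted p = 0.32 and 0.34).

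Camera called 19 of 35 lists in WD-fed liver (8 higher, 11 lower). Among these, acinar genes (mean -2.27, camera adjusted p = 0.047, and adjusted p = 0.753 with an estimated correlation) followed WT replicate 2, in which they stood out, and lay at -0.0118 without it (adjusted p = 0.739), at -2.27 without KO replicate 1 or 2 (adjusted p = 0.0614 and 0.0694) and at -2.26 without KO replicate 3 (adjusted p = 0.0644). Over all 14019 genes, 2943 were called in WD-fed liver, 1490 higher and 1453 lower in the livers labelled KO, 731 of them by a log2 of 1 or more. In 42.9% of genes, where chance gives 10%, the groups did not overlap. The balance of rises and falls depended on the scaling, at 970 and 1607 after median-of-ratios scaling and 1018 and 1365 after quantile normalization. The count was 1354 without WT replicate 1, 1619 without KO replicate 1, 1701 without WT replicate 3 and 1775 without KO replicate 3. It was 1701 among genes of at least 5 FPKM and 4462 with library weights. Of the 94 called genes named by the rule, 72 stayed past the threshold without any 1 of the 6 libraries. The calls of 21 ended without WT replicate 1 (adjusted p = 0.0504 to 0.176), 14 without KO replicate 1 (0.0523 to 0.157), 12 without KO replicate 3 (0.0540 to 0.147), 12 without WT replicate 3 (0.0566 to 0.112), 7 without KO replicate 2 (0.0558 to 0.126) and 1 without WT replicate 2 (0.0581). Of the genes given above, mt-Nd5 was among these, without WT replicate 1 (0.45, adjusted p = 0.101), WT replicate 3 (0.58, adjusted p = 0.0695), KO replicate 1 (0.58, adjusted p = 0.0715) and KO replicate 3 (0.48, adjusted p = 0.102).

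**Figure D3:**
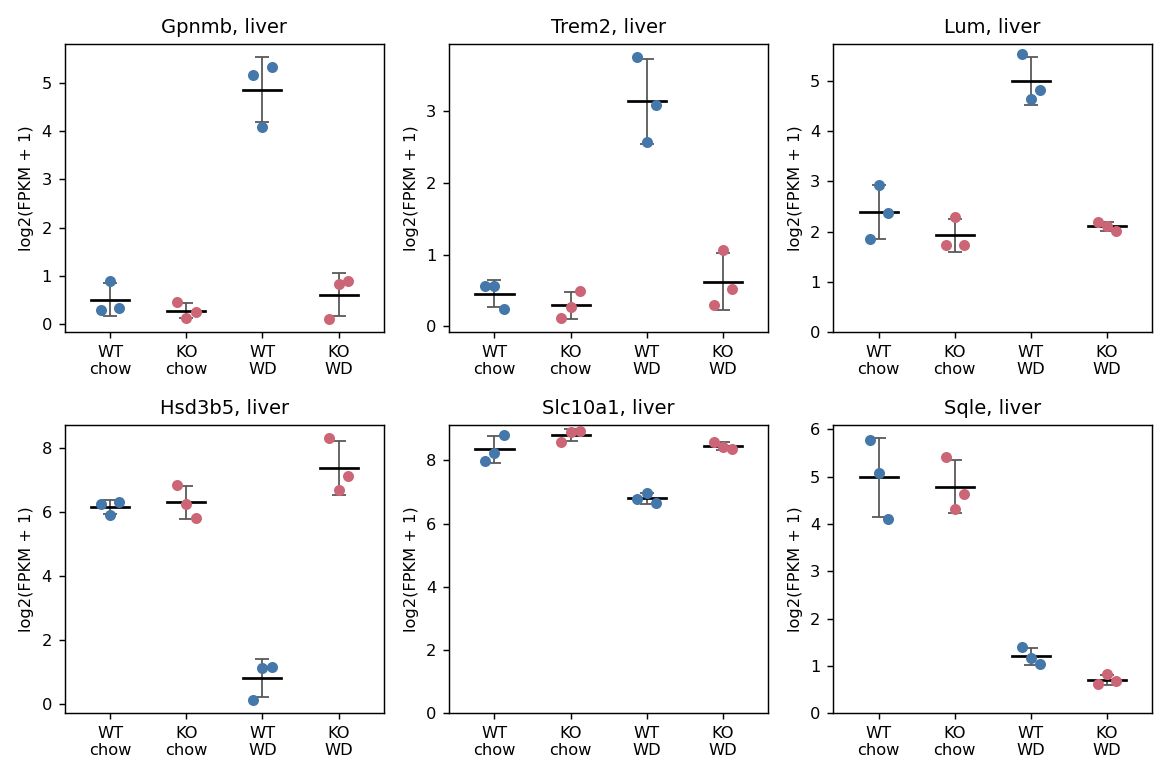
Log2(FPKM + 1) of 6 genes in the 12 liver libraries (blue WT, red KO), with the mean and SD of each group of 3 mice. Gpnmb, Trem2 and Lum are high in the 3 livers labelled WT WD, Hsd3b5 and Slc10a1 are low there, and Sqle is low on WD under both labels.

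In livers labelled WT, WD against chow asks for the diet's effect with Mrs2 present. Mrs2 levels on WD, whose order depended on the scaling, do not show whether the WD livers are as labelled. Cholesterol synthesis genes fell in 22 of 25 members, by a mean of -2.04 (camera adjusted p = 3.1e-16, and adjusted p = 0.199 with an estimated correlation), with squalene epoxidase Sqle down by 3.78 ± 0.38 (SE, n = 3 per group), Idi1 by 3.94 ± 0.44 and Msmo1 by 3.18 ± 0.31. Macrophage genes rose in 21 of 24 (mean 1.75, camera adjusted p = 5.2e-15, and adjusted p = 0.197 with an estimated correlation), with Gpnmb up by 4.36 ± 0.33 and the lectin Lgals3 by 3.10 ± 0.40. Matrix genes rose in 25 of 31 (mean 1.40, camera adjusted p = 3e-19, and adjusted p = 0.187 with an estimated correlation), including Mmp2 by 2.06 ± 0.20. Lipid droplet and uptake genes rose in 6 of 24 (mean 0.712, camera adjusted p = 0.0046, and adjusted p = 0.427 with an estimated correlation), with lipoprotein lipase Lpl up by 2.73 ± 0.25 and the fatty acid receptor Cd36 by 2.22 ± 0.39. Nuclear OXPHOS genes fell in 53 of 71 (mean -0.453, camera adjusted p = 2.3e-20, and adjusted p = 0.187 with an estimated correlation), with Ndufb9 down by 0.87 ± 0.10. Hsd3b5 fell by 5.35 ± 0.43 and Slc10a1 by 1.55 ± 0.20. Hepatocyte markers fell in 13 of 20 (mean -0.763, camera adjusted p = 1.1e-06, and adjusted p = 0.187 with an estimated correlation), a call that ended after quantile normalization. The hormone Fgf21 rose by 2.50 ± 0.33, within a fatty acid oxidation list of which 2 of 33 rose and 4 fell (mean -0.22, camera adjusted p = 0.023, and adjusted p = 0.714 with an estimated correlation). That list turned to 0.0336 after quantile normalization and lost its call without WT WD replicate 1 (-0.0576, adjusted p = 0.285) or WT chow replicate 3 (-0.139, adjusted p = 0.0976).

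In all, 2693 genes were called for diet in the livers labelled WT (1363 higher, 1330 lower on WD), 700 of them by a log2 of 1 or more, and camera called 21 of 35 lists. Groups did not overlap in 34.4% of genes, where chance gives 10%. Median-of-ratios scaling gave 1531 rises and 1007 falls. The count was 1425 without WT WD replicate 1, 1450 without WT chow replicate 3 (high in muscle genes) and 1467 without WT WD replicate 3, and 709 in a fit of these 2 groups alone. It was 1235 without the 2 livers high in muscle genes. Each gene named for this comparison so far kept its call without any 1 of the 6 libraries, as did 56 of the 67 called genes named by the rule, while mt-Nd6 (-0.50 to -0.59 without WT chow replicate 1 or 3 or WT WD replicate 1 or 3, adjusted p = 0.0505 to 0.0687) did not and turned after quantile normalization, to 0.0575.

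The same comparison in livers labelled KO has the same limit. Reads counted for Mrs2 gave 4.17 FPKM on chow and 4.51 on WD in them as means of 3, which does not show whether an intact transcript was present. Cholesterol synthesis genes fell, in 8 of 25 members over all genes tested and in 20 adjusted over the list alone, by a mean of -1.68 (camera adjusted p = 8.2e-25, and adjusted p = 0.42 with an estimated correlation). Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192) fell by 4.08 ± 0.38 (SE, n = 3 per group; limma adjusted p = 0.00149), from 28.2 ± 12.1 FPKM (SD) to 0.637 ± 0.117, and Msmo1 fell by 2.91 ± 0.31. The sterol exporters Abcg5 and Abcg8 rose by 1.97 ± 0.14 and 1.76 ± 0.16. Of 71 nuclear OXPHOS genes 2 fell over all genes tested and 20 adjusted over the list alone (mean -0.277, camera adjusted p = 5.1e-21, and adjusted p = 0.42 with an estimated correlation). Matrix genes had a mean of 0.317 (camera adjusted p = 0.00018, and adjusted p = 0.72 with an estimated correlation) and macrophage genes one of 0.334 (camera adjusted p = 0.0093, and adjusted p = 0.752 with an estimated correlation), with no member of either called. The macrophage call ended without KO WD replicate 2 (0.215, adjusted p = 0.126), which was high in muscle genes.

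With limma 59 genes were called for diet in the livers labelled KO (21 higher, 38 lower on WD) and 2152 had an unadjusted p under 0.05, while DESeq2 called 626 and library weights gave 383. Groups did not overlap in 26.8% of genes, where chance gives 10%. The count was 24 without KO WD replicate 3, 27 without KO chow replicate 3, 28 without KO chow replicate 1, 29 without KO WD replicate 1 and 36 without KO chow replicate 2. It was 21 without the livers high in acinar genes, 30 without the 2 WD livers whose Mrs2 lay beyond the other label, 34 with no filter on low values and 39 with a replicate block. Sqle, Msmo1, Abcg5 and Abcg8 kept their calls without any 1 of the 6 libraries. Across the 2707 genes called in either genotype, the diet effects under the labels WT and KO correlated at Pearson's r = 0.647 and Spearman's rho = 0.678, a description over genes, which are not independent replicates. Their median absolute log2 fold change was 0.676 under WT and 0.192 under KO, but 2693 of them were chosen by their call under WT. Over the 59 genes called under KO the medians were 1.004 and 1.27, and over all tested genes they were 0.241 and 0.161, with r at 0.333.

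The interaction of genotype and diet tests whether the diet's effect differed between the genotypes. In liver, with the labels as given, Hsd3b5 (6.42 ± 0.60; SE, n = 3 per group) and Slco1a1 (3.07 ± 0.29) responded to WD more positively in KO than in WT. Gpnmb (-4.03 ± 0.46), Fam83a (-3.00 ± 0.27), Shc2 (-2.49 ± 0.19) and Epcam (-1.57 ± 0.16) responded more negatively, and these 6 kept their calls without any 1 of the 12 libraries. Of 31 matrix genes 3 were called, all negative (mean -1.08, camera adjusted p = 8.9e-17, and adjusted p = 0.238 with an estimated correlation): Mmp2 (-1.68 ± 0.28), Lum (-2.43 ± 0.41) and Thbs2 (-1.03 ± 0.19). Of 24 macrophage genes 2 were, Gpnmb and Trem2 (-2.35 ± 0.40; mean -1.42, camera adjusted p = 2.5e-13, and adjusted p = 0.271 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.358 with none called (camera adjusted p = 0.037, and adjusted p = 0.706 with an estimated correlation), and that list's call ended without WT chow replicate 1 (0.0344, adjusted p = 0.804), KO chow replicate 2 (0.251, adjusted p = 0.189) or 3 (0.248, adjusted p = 0.135), WT WD replicate 3 (0.144, adjusted p = 0.395) or KO WD replicate 2 (0.328, adjusted p = 0.103) or 3 (0.327, adjusted p = 0.0649).

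With limma 77 genes were called for the interaction in liver (18 positive, 59 negative), edgeR called 16 and DESeq2 540. Leaving out each library in turn gave 35, 291 and 23 without WT chow replicates 1, 2 and 3, and 18, 21 and 15 without KO chow replicates 1, 2 and 3. It gave 39, 330 and 39 without WT WD replicates 1, 2 and 3, and 24, 35 and 37 without KO WD replicates 1, 2 and 3. The count was 13 with a pseudocount of 0.1, 6 among genes of at least 5 FPKM and 184 without the 2 WD livers whose Mrs2 lay beyond the other label. The calls of the 15 other called genes named by the rule ended without at least 1 library. Between 7 and 15 of the rule's 21 ended without each of 10 libraries (adjusted p = 0.0506 to 0.133), and 0 without WT chow or WT WD replicate 2. Trem2, Mmp2, Lum and Thbs2 each lost the call without 9 or more libraries.

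In iWAT on chow the comparison of KO with WT asks what loss of Mrs2 does to subcutaneous fat. The KO libraries stood higher in thermogenic and oxidative genes. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), the uncoupling protein of thermogenic fat, stood at 113 ± 38.3 FPKM (SD, n = 3) in KO and 0.222 ± 0.300 in WT, a log2 fold change of 6.53 ± 1.11 (SE). Thermogenic genes stood higher in 17 of 19 members, by a mean of 1.52 (camera adjusted p = 4.9e-14, and adjusted p = 0.287 with an estimated correlation), and 10 passed adjusted over the list alone, including Ucp1, the elongase Elovl3 (4.13 ± 0.74) and the deiodinase Dio2 (1.25 ± 0.26). TCA cycle and pyruvate dehydrogenase genes stood higher in 24 of 24, by a mean of 0.607 (camera adjusted p = 2.1e-27, and adjusted p = 0.287 with an estimated correlation). Of these, 20 passed adjusted over the list alone, such as the pyruvate carrier Mpc2 (0.82 ± 0.12). Nuclear OXPHOS genes stood higher in 70 of 71, by a mean of 0.415 (camera adjusted p = 6.1e-41, and adjusted p = 0.287 with an estimated correlation), and mitochondrially encoded ones had a mean of 0.694 (camera adjusted p = 1.3e-06, and adjusted p = 0.555 with an estimated correlation). Fatty acid oxidation genes had a mean of 0.599 (camera adjusted p = 8.7e-17, and adjusted p = 0.287 with an estimated correlation), and 9 of 29 passed adjusted over the list alone, including the droplet protein Plin5 (1.84 ± 0.31). Lipogenesis genes had a mean of 0.370 (camera adjusted p = 7.7e-05, and adjusted p = 0.593 with an estimated correlation), with the elongase Elovl6 at 1.49 ± 0.34, but that call ended without WT replicate 3 (0.171, adjusted p = 0.115), which was high in lymphocyte genes.

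No single gene was called in iWAT on chow. With limma the count was 0 of 14685, the smallest adjusted p was 0.410 and 830 genes had an unadjusted p under 0.05, while edgeR called 0 and DESeq2 66. Groups did not overlap in 10.8% of genes, where chance gives 10%. With a replicate block the count was 1, with a block in a fit of these 2 groups alone 0, without KO replicate 1 it was 1, and with no filter on low values or in a fit of the 2 groups alone 1. The numbers 3 in this comparison were the libraries high in lymphocyte genes, whose list level was 4.10 in WT and 3.95 in KO. Camera called 15 of 32 lists, and 6 of them (thermogenic, TCA cycle, both OXPHOS lists, fatty acid oxidation, and gluconeogenesis and glycolysis) kept the call without any 1 of the 6 libraries. With a block in a fit of these 2 groups alone, 14 of the 15 list calls held and 1 ended, while 4 lists not called before passed.

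On WD the same groups of genes rose in KO iWAT, and single genes passed. Ucp1 stood at 493 ± 316 FPKM (SD, n = 3; 651, 699 and 129 per library) in KO and 18.5 ± 15.9 in WT, a rise of 5.30 ± 1.11 (SE; limma adjusted p = 0.0311). The droplet protein Cidea rose by 4.12 ± 0.61, Elovl3 by 5.28 ± 0.74, the cytochrome oxidase subunit Cox8b by 3.37 ± 0.63 and the fatty acid binding protein Fabp3 by 5.39 ± 1.03. Cox8b and Fabp3 are also expressed in muscle, whose marker list stood lower in KO (mean -1.78). Thermogenic genes rose in 14 of 19 members (mean 2.22, camera adjusted p = 5.3e-17, and adjusted p = 0.185 with an estimated correlation). TCA cycle genes rose in 22 of 24 (mean 0.998, camera adjusted p = 1.1e-24, and adjusted p = 0.185 with an estimated correlation), with Mpc2 up by 1.03 ± 0.12 (limma adjusted p = 0.0072). Nuclear OXPHOS genes rose in 38 of 71 (mean 0.695, camera adjusted p = 9.7e-40, and adjusted p = 0.185 with an estimated correlation), and mitochondrially encoded ones in 9 of 13 (mean 1.97, camera adjusted p = 3.9e-14, and adjusted p = 0.185 with an estimated correlation), with mt-Nd2 up by 2.05 ± 0.30. Fatty acid oxidation genes rose in 17 of 29 and fell in 1 (mean 1.10, camera adjusted p = 1e-19, and adjusted p = 0.185 with an estimated correlation).

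Genes of fat synthesis rose as well. Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495) rose by 3.55 ± 0.34 (SE, n = 3 per group; limma adjusted p = 0.00397) and acetyl-CoA carboxylase Acaca by 1.79 ± 0.20 (limma adjusted p = 0.00497), and 10 of 23 lipogenesis genes rose with none lower (mean 1.12, camera adjusted p = 1.2e-13, and adjusted p = 0.185 with an estimated correlation). Genes of gluconeogenesis and glycolysis, tested as 1 list, rose in 3 of 21 (mean 0.600, camera adjusted p = 1.6e-09, and adjusted p = 0.185 with an estimated correlation). The calcium and proton exchanger of mitochondria Letm1 rose by 1.10 ± 0.15, 1 of 2 risen in a list of 13 genes of mitochondrial calcium transport (mean 0.321, camera adjusted p = 0.00082, and adjusted p = 0.295 with an estimated correlation). Among the falls were the imprinted gene Peg3 (-1.99 ± 0.39), the oxytocin receptor Oxtr (-2.02 ± 0.35) and the chemokine Ccl2 (-1.94 ± 0.44). Macrophage genes had a mean of -0.385 with no member of 24 called (camera adjusted p = 0.00073, and adjusted p = 0.46 with an estimated correlation), and that call ended without KO replicate 3 (-0.223, adjusted p = 0.057). Matrix genes fell in 1 of 31, Thbs2 by 1.36 ± 0.28 (mean -0.500, camera adjusted p = 0.00082, and adjusted p = 0.537 with an estimated correlation). Red cell genes, highest in WT replicate 1 at a level of 8.35, fell in 2 of 6 (mean -1.82, camera adjusted p = 2.4e-05, and adjusted p = 0.295 with an estimated correlation). Muscle genes stood lower in KO by a mean of 1.78 with none called, an order that the test turned with library weights (mean -0.383), and lymphocyte genes higher by 0.727. Both list calls ended without single libraries, muscle without WT replicate 1 (-0.562, adjusted p = 0.808), KO replicate 2 (-0.972, adjusted p = 0.244) or KO replicate 3 (-1.11, adjusted p = 0.47), and lymphocyte without KO replicate 2 (0.182, adjusted p = 0.597), WT replicate 2 (0.587, adjusted p = 0.102) or WT replicate 3 (0.569, adjusted p = 0.124). At the preset correlation camera gave adjusted p = 0.029 and 0.021 for these lists, and adjusted p = 0.635 for each with an estimated correlation.

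Camera called 19 of 32 lists in WD-fed iWAT (14 higher, 5 lower). By limma 624 genes were called in WD-fed iWAT (470 higher, 154 lower in KO), 225 of them by a log2 of 1 or more, while edgeR called 631 and DESeq2 1356. In 25.01% of genes the groups did not overlap, where chance gives 10%. The count fell to 16 without KO replicate 2 (high in lymphocyte genes), 17 without KO replicate 1 (high in muscle genes), 26 without WT replicate 3, 215 without WT replicate 2 and 253 without WT replicate 1 (high in muscle genes). It was 16 in a fit of these 2 groups alone, 4 without the libraries high in muscle genes, 15 without those high in lymphocyte genes, 204 with no filter on low values and 1514 with library weights. Of the 61 called genes named by the rule only Elovl6, Acaca and Mpc2 stayed past the threshold without any 1 of the 6 libraries. The calls of 58 ended without KO replicate 2 (adjusted p = 0.0581 to 0.179), 57 without KO replicate 1 (0.0715 to 0.182), 56 without WT replicate 3 (0.0534 to 0.183), 28 without WT replicate 2 (0.0504 to 0.126), 25 without WT replicate 1 (0.0502 to 0.106) and 4 without KO replicate 3 (0.0667 to 0.0910). Ucp1 had 4.93 without KO replicate 1, 4.88 without KO replicate 2 and 3.76 without WT replicate 3 (adjusted p = 0.128, 0.122 and 0.0656).

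**Figure D4:**
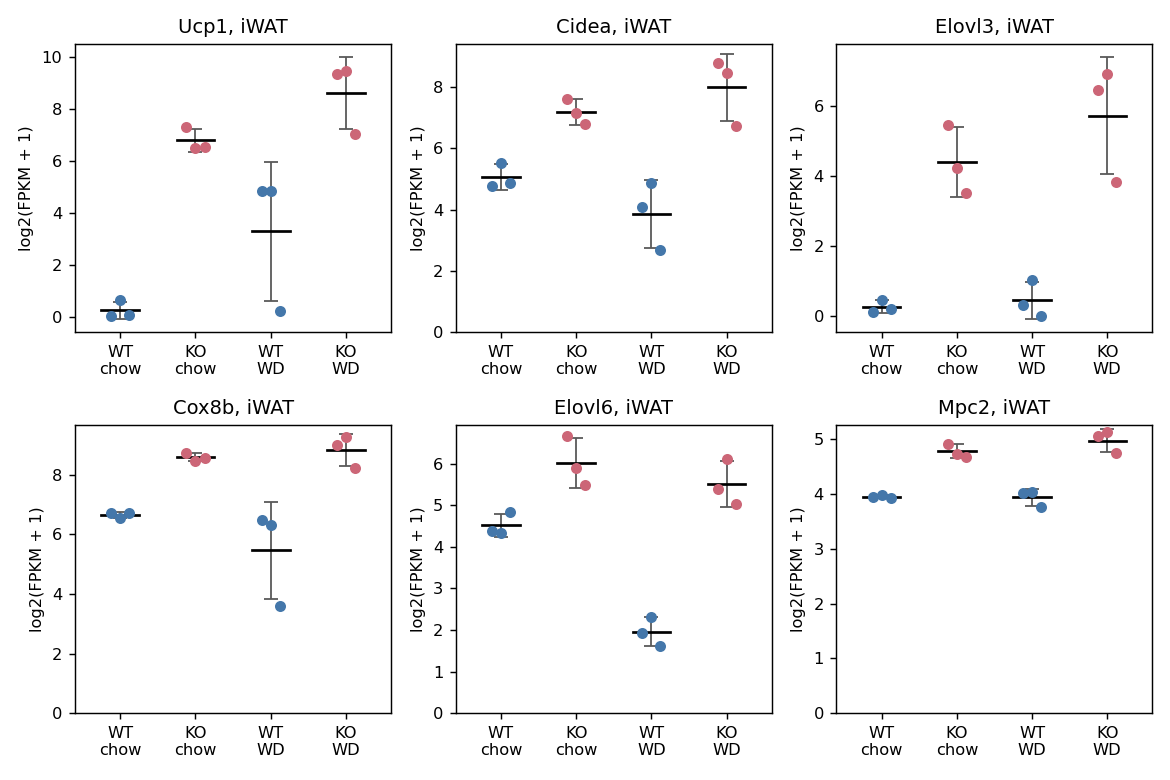
Log2(FPKM + 1) of 6 genes in the 12 iWAT libraries (blue WT, red KO), with the mean and SD of each group of 3 mice. On each diet Ucp1, Elovl3, Cidea and Mpc2 are higher in all 3 KO libraries than in the 3 WT libraries, and Elovl6 is lowest in WT WD, at 2.97 ± 0.954 FPKM.

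WD against chow in WT iWAT lowered fat synthesis genes. Elovl6 fell by 2.56 ± 0.34 (SE, n = 3 per group; limma adjusted p = 0.0136), Acaca by 1.63 ± 0.20 (limma adjusted p = 0.0107) and fatty acid synthase Fasn by 1.96 ± 0.37, and 6 of 23 lipogenesis genes fell, or 14 adjusted over the list alone (mean -0.868, camera adjusted p = 1.9e-09, and adjusted p = 0.586 with an estimated correlation). The largest falls were the detoxification genes Cyp2e1 (-4.73 ± 0.46) and Cyp2f2 (-4.18 ± 0.57). The imprinted genes Mest (4.71 ± 1.02) and Peg3 (3.22 ± 0.39) rose, as did Oxtr (2.61 ± 0.35) and Ccl2 (2.43 ± 0.44). Matrix genes rose in 3 of 31 (mean 0.772, camera adjusted p = 1.7e-05, and adjusted p = 0.653 with an estimated correlation), and macrophage genes had a mean of 0.528 with none called (camera adjusted p = 0.00024, and adjusted p = 0.586 with an estimated correlation). Lymphocyte genes, which stood out in WT chow replicate 3, had a mean of -1.40 with none called (camera adjusted p = 5.9e-06, and adjusted p = 0.636 with an estimated correlation). Muscle genes had a mean of 2.76 with none called (camera adjusted p = 0.00079, and adjusted p = 0.775 with an estimated correlation). That call ended without WT WD replicate 1 (1.54, adjusted p = 0.112). Red cell genes rose in 1 of 6, Alas2 by 2.08 ± 0.43, or in all 6 adjusted over the list alone (mean 1.72, camera adjusted p = 0.00017, and adjusted p = 0.586 with an estimated correlation). Thermogenic genes were not among the 12 lists called. Mitochondrially encoded OXPHOS genes stood at mean log2 levels of 8.48, 8.51 and 7.96 on chow and 8.12, 7.96 and 7.45 on WD.

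In total 312 genes were called for diet in WT iWAT (199 higher, 113 lower on WD), and DESeq2 called 1600. Without overlap between the groups were 27.3% of genes, where chance gives 10%. The count was 22 without WT WD replicate 3, 31 without WT WD replicate 2, 38 without WT chow replicate 2, 84 without WT chow replicate 3 and 137 without WT chow replicate 1. It was 95 in a fit of these 2 groups alone, 99 and 136 without the libraries high in lymphocyte and in muscle genes, 139 with no filter on low values, 155 with a replicate block and 837 with library weights. Of the 20 called genes named by the rule, Acaca, Peg3, Cyp2e1 and the thiosulfate transferase Tst (-2.48 ± 0.25) stayed past the threshold without any 1 of the 6 libraries. The calls of 16 ended without WT WD replicate 3 (adjusted p = 0.0572 to 0.142), 13 without WT WD replicate 2 (0.0538 to 0.145), 13 without WT chow replicate 2 (0.0523 to 0.121), 9 without WT chow replicate 3 (0.0561 to 0.119), 7 without WT chow replicate 1 (0.0554 to 0.109) and 3 without WT WD replicate 1 (0.0768 to 0.0814). Elovl6 had -2.40 without WT WD replicate 3 (adjusted p = 0.0573), and Mest lost the call without each of the 6 libraries (4.20 to 5.53).

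In KO iWAT, oxidative genes stood higher on WD than on chow as groups. Fatty acid oxidation genes had a mean of 0.635 (camera adjusted p = 8.7e-12, and adjusted p = 0.538 with an estimated correlation), and adjusted over the list alone 3 of 29 passed, the thiolase Acaa1b (1.54 ± 0.31; SE, n = 3 per group) and the carnitine transferases Cpt1a and Cpt1b. Thermogenic genes had a mean of 0.807 (camera adjusted p = 1.3e-05, and adjusted p = 0.566 with an estimated correlation), with the potassium channel Kcnk3 at 0.85 ± 0.22. Genes of the circadian clock had a mean of -0.526 (camera adjusted p = 0.0001, and adjusted p = 0.538 with an estimated correlation), and the labels give no hour of collection. These 3 list calls held without any 1 of the 6 libraries. Markers of other tissues moved too, with no member called. Muscle genes had a mean of 1.67 (camera adjusted p = 0.0033, and adjusted p = 0.657 with an estimated correlation). This ended without KO WD replicate 1 (0.200, adjusted p = 0.872). Lymphocyte genes had one of -0.870 (camera adjusted p = 0.00014, and adjusted p = 0.597 with an estimated correlation). Their call ended without KO chow replicate 3 (-0.436, adjusted p = 0.0658) or KO WD replicate 3 (-0.325, adjusted p = 0.160). With limma 0 genes were called, the smallest adjusted p was 0.225 and 1390 had an unadjusted p under 0.05, while edgeR called 0 and DESeq2 132. The share of genes without overlap between the groups was 15.1%, where chance gives 10%. The count was 49 without KO WD replicate 3, 1 without KO chow replicate 1, 31 with library weights and 1 with no filter on low values or in a fit of these 2 groups alone. Across the 312 genes called in WT, the diet effects in WT and KO correlated at Pearson's r = 0.824 and Spearman's rho = 0.789 over genes, which are not independent replicates, with median absolute log2 fold changes of 0.906 and 0.291, a gap that the choice of genes by their call in WT favours. Over all tested genes the medians were 0.183 and 0.139 and r was 0.576. It was 0.434 among the called genes without KO WD replicate 3, 0.588 without WT chow replicate 2, 0.659 without KO chow replicate 1 and 0.687 without KO chow replicate 3.

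For the interaction in iWAT, lipogenesis genes responded to WD more positively in KO, with a mean of 0.750 (camera adjusted p = 1.6e-09, and adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone Elovl6 (2.05 ± 0.48; SE, n = 3 per group), Acaca (1.11 ± 0.28) and the triglyceride enzyme Dgat1 (0.58 ± 0.15) passed. Mitochondrially encoded OXPHOS genes had a mean of 1.28 (camera adjusted p = 1.5e-08, and adjusted p = 0.545 with an estimated correlation) and thermogenic genes one of 0.700 (camera adjusted p = 1.5e-05, and adjusted p = 0.545 with an estimated correlation), with the adrenergic receptor Adrb3 at 2.17 ± 0.40. These 3 list calls held without any 1 of the 12 libraries. Part of the mean for mitochondrially encoded OXPHOS genes was a lower level on WD in WT (8.12, 7.96 and 7.45 against 8.48, 8.51 and 7.96 on chow). With limma 0 genes were called, the smallest adjusted p was 0.0610 and 1011 had an unadjusted p under 0.05, while edgeR called 0 and DESeq2 44. The count was 8 without KO WD replicate 3, 2 without WT WD replicate 3, 1 without WT chow replicate 1 or 2 or KO chow replicate 1, 2 with library weights, and 1 among genes of at least 5 FPKM or after median-of-ratios scaling.

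**Figure D5:**
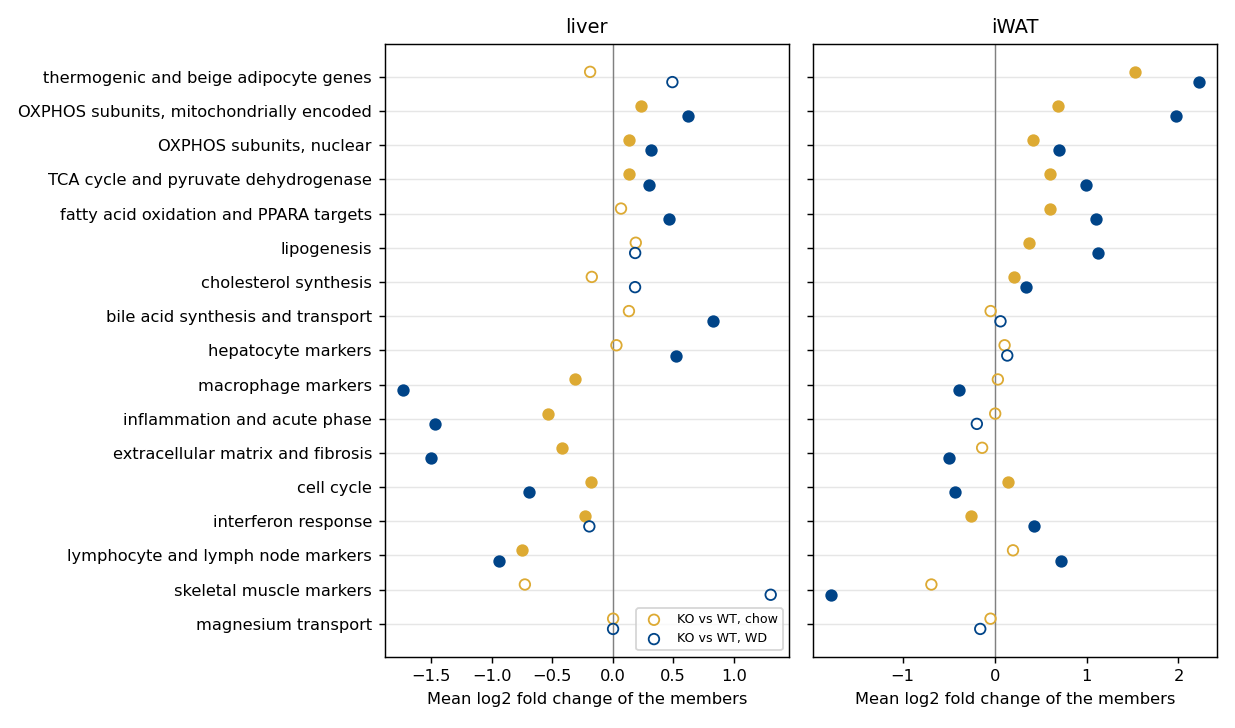
Mean log2 fold change of KO over WT for 17 gene lists on chow (yellow) and WD (blue) in liver and iWAT, where a filled symbol is a camera adjusted p under 0.05. Macrophage and matrix genes lie at -1.74 and -1.501 in WD-fed liver, thermogenic genes at 1.52 and 2.22 in iWAT, and other scalings turn, in liver, the hepatocyte list on WD (0.522, or -0.136 after quantile normalization) and uncalled lists (lipogenesis on WD, fatty acid oxidation and hepatocytes on chow, magnesium transport on both diets).

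The authors' deposited tables of KO against WT list genes with an unadjusted p under 0.05. By their adjusted p under 0.05 they hold 10 genes in liver on chow, 104 in iWAT on chow, 4217 in liver on WD and 1281 in iWAT on WD. The 104 included Ucp1 (log2 fold change 9.03, the authors' adjusted p = 5.62e-12), Elovl3 (6.85, 4.43e-24), Letm1 (0.727, 0.00228) and Me1 (0.898, 0.0258), which limma did not call on chow. Others named above, such as Acaca (0.729, 0.136), did not pass in their table either. Of the 2943 genes called here in WD-fed liver 2591 were also called in their table, and of the 624 in WD-fed iWAT 575 were. The sign was equal for all of the authors' called genes that were tested here (10, 100, 3420 and 1186). Both sets of calls rest on the same reads, so the shared calls and signs are no independent support. In their pathway table for iWAT on chow, 88 listed genes of thermogenesis (87 higher in KO) and 77 of oxidative phosphorylation (76 higher) were counted. For WD-fed liver it counted 58 of complement and coagulation, the pathway with the authors' smallest adjusted p (34 higher and 24 lower in the livers labelled KO), 57 of hematopoietic cell lineage (53 lower) and 50 of matrix and receptor interaction (46 lower).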

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

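The tests with the muscle and lymphocyte levels, of the macrophage against the endothelial genes, of both scalings and of Gpld1 were chosen after the result was seen, while the regrouping of libraries, the brown fat markers and the exchange of labels were chosen before.

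In iWAT the thermogenic list stood higher in KO than in WT by 1.52 on chow and 2.22 on WD (SE 0.378 each, n = 3 per group), and its response to WD differed by 0.700 ± 0.535, within 2 SE of 0. Muscle RNA and lymph node RNA are argued against: with the muscle level in the model the difference was 1.63 ± 0.328 on chow and 2.50 on WD, and with the lymphocyte level 1.49 ± 0.387 and 2.11. Brown fat carried into the KO samples stays open. Its marker Lhx8 overlapped on chow (1.12 to 2.29 FPKM in KO, 0.764 to 2.15 in WT), and on WD it was lower in all 3 KO libraries (0.963 to 1.25) than in all 3 WT libraries (1.76 to 2.54), opposite to what brown fat would bring. Neither outcome set in advance was met. The WT level of Lhx8 would hide a small share, Zic1 lay near the floor in all 12 libraries (at most 0.0922 FPKM), and no brown fat library sets the share needed. An effect of genotype on white or beige fat cells may account for the pattern and stays open beside it.

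In liver on WD macrophage and matrix genes fell by means of 1.74 and 1.501 in the livers labelled KO, and hepatocyte genes rose by a mean of 0.522 that quantile normalization turned. A larger share of hepatocyte RNA alone is argued against, since it would lower the markers of other cell types alike, and the macrophage level changed by -1.51 ± 0.303 relative to the endothelial level (-1.71 with a pseudocount of 0.1). Scaling is argued against for the immune and matrix genes, whose smaller mean fall under another scaling was -1.54. Its SE of 0.136 was taken over the 31 matrix genes, which are not independent replicates, and not over mice. For the hepatocyte genes the criterion stated for scaling was met, since their mean was -0.136 after quantile normalization (SE 0.107 over the 20 genes, not over mice). That normalization makes the highest values of the libraries equal, however. It can thus remove a joint rise of genes that lay at mean log2 levels of 10.1 to 11.3. Median-of-ratios scaling kept a mean of 0.439 with 17 of the 20 genes positive, so scaling is neither shown nor excluded as the source of the rise. A change in the immune and scar-forming cells themselves stays open for the rest, as do the genotype and the labels of these livers, and none of these was tested apart from the others.

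Mrs2 in WD-fed liver lay at 4.10 to 5.21 FPKM in the libraries labelled KO and 4.10 to 5.11 in those labelled WT. Exchanging replicate 2 between the labels left 2 called genes in place of 2943, which met the criterion stated against an exchange. No other split of these 6 libraries gave more than 2, however. The count thus shows that the 3 livers under each label resemble each other, and it cannot decide whether their genotypes are as labelled. Reads of the overlapping Gpld1 stay open: over the 12 livers Mrs2 rose by 0.0347 ± 0.0112 FPKM per FPKM of Gpld1 with genotype in the model, which met the criterion stated for that source, but the slope within the 4 groups was 0.00118 ± 0.0339 (SE), so it cannot be told apart from diet and genotype. That second condition was added after the first value was seen. Scaling of the libraries stays open too, since in recovered reads KO replicate 2 lay below WT replicates 1 and 3 (541 against 625 and 630). The lymphocyte list's level was 0.843 to 0.874 in the livers labelled KO WD and 0.875 to 0.953 in KO chow. It was 1.49 to 1.96 in those labelled WT WD and 1.22 to 2.09 in WT chow. In this list the WD livers thus lay with the chow livers of their label, but it is 1 of 35, picked after its values were seen, and no test of genotype. A single wrong label, an exchange with a mouse outside these groups and a partial loss of the transcript that differs between diets also stay open, and were not tested.

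Chance was examined by regrouping the libraries. The 10 splits of 6 libraries are too few for a share under 0.05. In liver the real split gave 2943 genes for KO against WT on WD (1 of 10 splits gave as many, highest other 2). For WD against chow it gave 2693 in WT (1 of 10, highest other 3) and 59 in KO (1 of 10, highest other 5). In iWAT it gave 624 for KO against WT on WD (1 of 10, highest other 3). For WD against chow it gave 312 in WT iWAT (1 of 10, highest other 2). For the interaction, 11 of 100 regroupings in liver gave at least the real 77 genes, with 2061 as the highest other, which met the criterion stated for chance. All 11 kept the WD groups intact, however, and so held the real contrast on WD, while the highest count among the others was 2. Seen after the result, this leaves the regrouping unable to decide about chance. Where the real count was 0, as for the interaction in iWAT, regrouping decides nothing.

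The diet's effect differed between the genotypes, by the interaction term of limma, for 77 genes in liver with the labels as given. Those named by the rule that were more positive in KO, as log2 fold changes, were Hsd3b5 (6.42), Slco1a1 (3.07), Susd4 (2.50), Ttc39c (1.72), Zfp36 (1.43) and Car5a (1.05). Those more negative were Ly6d (-4.67), Gpnmb (-4.03), Fam83a (-3.00), Sprr1a (-2.77), Cd63 (-2.74), Shc2 (-2.49), Lum (-2.43), Trem2 (-2.35) and Cbr3 (-2.30). Mmp2 (-1.68), Epcam (-1.57), Mmp7 (-1.42), Sox4 (-1.27), Pdgfrb (-1.14) and Thbs2 (-1.03) were negative too.

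By camera at the preset correlation the interaction also passed for 23 lists in liver and 13 in iWAT, none of which held with an estimated correlation. In liver the means for muscle (2.03) and acinar genes (-4.63) came from the livers high in these genes. Without those livers both calls ended, and the muscle list turned (mean 0.0203 with a negative test). The mean was positive for male-biased and Y-linked (1.91), bile acid (0.692), xenobiotic (0.652), fatty acid oxidation (0.397), endoplasmic reticulum stress (0.381), cholesterol synthesis (0.358) and TCA cycle genes (0.161). It was positive too for hepatocyte (0.493), mitochondrially encoded OXPHOS (0.382) and nuclear OXPHOS genes (0.176), which quantile normalization turned (means -0.0499, 0.0402 with a negative test, and -0.00864). It was negative for tumour and fetal liver (-1.45), macrophage (-1.42), matrix (-1.08), inflammation (-0.931), bile duct (-0.751), cell cycle (-0.512) and antioxidant genes (-0.485). HIF1A targets (-0.302), stellate cell (-0.296), endothelial (-0.244) and gluconeogenesis and glycolysis genes (-0.183) were negative as well. In iWAT it was positive for mitochondrially encoded OXPHOS (1.28), lipogenesis (0.750), thermogenic (0.700), interferon (0.684), fatty acid oxidation (0.502), TCA cycle (0.391), nuclear OXPHOS (0.281), gluconeogenesis and glycolysis (0.259) and antioxidant genes (0.163). It was negative for red cell (-1.57), cell cycle (-0.577), macrophage (-0.421) and matrix genes (-0.364).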

How the results depend on the processing

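The alternatives that leave out libraries high in muscle, acinar or lymphocyte genes, or the WD livers whose Mrs2 lay beyond the other label, were chosen after the results were seen, as was the block within 2 groups, and the others before. Over all alternatives, named genes called in the report kept direction and call in 4671 cases, lost the call in 1106 and turned in 4, and called lists kept both in 2834, lost the call in 547 and turned in 11. Genes not called stayed so with 1 sign in 8290 cases, changed sign without a call in 25 and passed in 247. For lists not called these numbers were 2886, 272 and 223, and 2 more passed with the opposite sign. Unless a cause is given, the cause was not tested.

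DESeq2 on recovered reads gave 16 for KO against WT on chow in liver, 626 for diet in KO liver and 540 for the liver interaction. In iWAT it gave 66 and 1356 for KO against WT on chow and WD, 1600 and 132 for diet in WT and KO, and 44 for the interaction. EdgeR moved only the liver interaction by more than 1.5 times, to 16. Library weights gave 4462 for KO against WT on WD in liver, 383 for diet in KO liver, 154 for the liver interaction, 1514 for KO against WT on WD in iWAT, 837 and 31 for diet in WT and KO iWAT, and 2 for the iWAT interaction. They also turned the test of muscle genes for KO against WT on WD in iWAT (mean -0.383). The variance prior without robust fitting moved no count by more than 1.5 times.

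Filters act by construction through the genes tested. With no filter the count was 3 for KO against WT on chow in liver, 34 for diet in KO liver and 50 for the liver interaction. In iWAT it was 1 and 204 for KO against WT on chow and WD, and 139 and 1 for diet in WT and KO. Among genes of at least 5 FPKM it was 1701 for KO against WT on WD and 1606 for diet in WT in liver, 6 for the liver interaction and 1 for the iWAT interaction. A log2 fold change of at least 1, which can only remove calls, left 731, 700 and 39 for KO against WT on WD, diet in WT and diet in KO in liver, and 225 and 130 for KO against WT on WD and diet in WT in iWAT. A pseudocount of 0.1 gave 13 for the liver interaction.

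In a fit of the libraries of 2 groups alone, which leaves fewer degrees of freedom and cannot give an interaction, the count was 709 for diet in WT liver, and in iWAT 1 and 16 for KO against WT on chow and WD, and 95 and 1 for diet in WT and KO. A replicate block gave 39 for diet in KO liver, 20 for the liver interaction, 1 for KO against WT on chow in iWAT and 155 for diet in WT iWAT, and moved no other count by more than 1.5 times. Equal numbers were not shown to mark a pair of mice. No list call held with an estimated correlation, and fry called 0 and 20 lists for KO against WT on chow and WD, 19 and 3 for diet in WT and KO and 8 for the interaction in liver, and 0, 10, 1, 1 and 0 in iWAT.

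Median-of-ratios scaling gave 1 for the iWAT interaction. Quantile normalization gives all libraries the same distribution, so by construction it can remove a joint change of the most abundant genes. Quantile normalization turned mt-Nd6 (-0.0603), mt-Nd5 (-0.250), Apoa2 (-0.0704) and the hepatocyte list (-0.136) for KO against WT on WD in liver, and mt-Nd6 (0.0575) and the fatty acid oxidation list (0.0336) for diet in WT liver. For the liver interaction it turned the tests of nuclear OXPHOS (mean -0.00864), mitochondrially encoded OXPHOS (0.0402) and hepatocyte genes (-0.0499). The largest shift of the median over all genes was -0.0630, with median-of-ratios scaling for KO against WT on WD in liver.

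Leaving out libraries high in muscle genes gave 3 for KO against WT on chow in liver, 1235 for diet in WT liver, 17 for the liver interaction, 4 for KO against WT on WD in iWAT and 136 for diet in WT iWAT. It turned the muscle list itself in liver, for KO against WT on chow (0.573) and for the interaction (0.0203). On chow that list was not called before and then passed. KO chow replicate 2, at a muscle level of 1.74, was not left out, so not all of the muscle signal was removed. Leaving out livers high in acinar genes gave 21 for diet in KO liver, and leaving out iWAT libraries high in lymphocyte genes gave 15 for KO against WT on WD and 99 for diet in WT. Without the WD livers whose Mrs2 lay beyond the other label, diet in KO liver gave 30, the liver interaction gave 184 and its interferon list turned (-0.275).

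Without 1 library at a time, counts in liver ran from 0 to 2 and 1354 to 2998 for KO against WT on chow and WD, 1425 to 2791 and 24 to 53 for diet in WT and KO, and 15 to 330 for the interaction. In iWAT they ran from 0 to 1 and 16 to 871 for KO against WT on chow and WD, 22 to 287 and 0 to 49 for diet in WT and KO, and 0 to 8 for the interaction. The correlation of diet effects ran from 0.571 to 0.722 in liver and 0.434 to 0.871 in iWAT, and over all tested genes it was 0.333 and 0.576. For KO against WT on chow in liver, the tests turned for endoplasmic reticulum stress genes without WT replicate 1 (mean 0.0813, range over the libraries -0.543 to 0.0813), macrophage genes without WT replicate 2 (-0.0141, range -0.472 to -0.0141) and acinar genes without KO replicate 1 (0.0331, range 0.0331 to 3.58). Nuclear OXPHOS genes turned for diet in WT iWAT without WT WD replicate 3 (0.0373, range -0.193 to 0.0373). Depth was 14.7 to 20.4 M recovered reads per library and was not varied. On simulated reads at these depths with 3 mice per group, changes of a log2 of 1 were recovered in 36.7% of cases for KO against WT on WD in liver and in 6.06% for the liver interaction. Those reads held no correlation between genes and no library high in markers of another tissue.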

Other observations

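The count of genes common to all comparisons and its regroupings were chosen after the result was seen, and the test of genes near Mrs2 before.

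Some genes stood apart between genotypes in both tissues and on both diets. Of 12296 genes tested in both tissues, 18 had an unadjusted p under 0.05 (limma) in all 4 comparisons of KO with WT, and 15 of these had 1 sign throughout, against 0.304 expected if the comparisons were independent and at most 1 in 99 regroupings drawn apart in each tissue. Neither figure tests for a common effect. Both comparisons of a tissue share 1 residual variance per gene, so they are not independent. Regrouping moves real differences between the groups into that variance, which lowers the counts. Mice shared by the tissues would raise such agreement too. When libraries of equal number were regrouped alike in both tissues, none of the 199 other counts reached 15, which met the criterion stated against shared mice. The highest was 13, though, and these counts are lowered in the same way. A wider margin was asked for after that value was seen, so shared mice stay open. On chow none of the 18 genes passed by limma after adjustment over all genes. In the authors' values those that passed in iWAT on chow included Letm1, Me1 and Pkm (the authors' adjusted p = 0.00228, 0.0258 and 0.0345). Higher in KO (n = 3 per group) were Letm1, which exchanges cations across the inner mitochondrial membrane (log2 fold change 0.35 in liver on chow, 0.61 in the WD livers labelled KO, 0.63 in iWAT on chow and 1.10 in iWAT on WD), Me1, the malic enzyme (0.87, 0.90, 0.87 and 1.58), glycerol kinase Gk (0.29, 0.46, 1.49 and 2.47) and Pank1, which starts the synthesis of coenzyme A (0.42, 1.04, 1.16 and 2.14). The others were Emc6, Fh1, Gsk3a, Mrpl34, Mrpl43, Ndufa8, Paqr9, Pdhb, Pygl and Tfb2m, all higher, and Rarg, lower. Pyruvate kinase Pkm went opposite ways, at -0.53 and -1.61 in liver on chow and WD and at 0.69 and 0.78 in iWAT, as did Rtn4 and Sorl1 between the tissues. A genotype effect common to both tissues could account for the 15 genes, which were chosen after their values were seen, and it is a hypothesis found and tested on the same libraries.

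Leptin, a hormone that fat cells release as they enlarge, stood in iWAT at 167 ± 72.8 FPKM (SD, n = 3) in WT chow, 188 ± 93.2 in KO chow, 571 ± 197 in WT WD and 203 ± 118 in KO WD. Lep was chosen after its values were seen. In liver the hormone Fgf21 stood at 1.76 FPKM in WT chow, 1.94 in KO chow, 15.5 ± 6.62 in the livers labelled WT WD and 6.21 ± 3.05 in those labelled KO WD. The B cell gene Cd79a was lower in the livers labelled KO on both diets, at a mean of 0.558 against 2.49 FPKM on chow and 0.505 against 2.33 on WD. Nnt, the mitochondrial transhydrogenase of which the C57BL/6J strain carries a deletion, stood at 0.361 FPKM or less in all 24 libraries, with 3 to 32 reads each, under both genotypes, and the labels do not name the strain.

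A knockout can alter genes beside it, through the construct or through strain sequence carried along. Within 1 Mb of Mrs2, 3 of 17 tested genes (17.6%; Carmil1, Gm23340 and Aldh5a1) had an unadjusted p under 0.05 (limma) with 1 sign in at least 2 of the 4 comparisons of KO with WT, against 1518 of 16408 (9.25%), with a one-sided Fisher's exact p of 0.204. With so few genes nearby, an effect on neighbours was neither shown nor excluded.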
